A study of Mus musculus with 4 samples.

How the data were processed

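The data were gene expression profiles of mouse bone marrow-derived macrophages, measured on 4 Affymetrix whole-transcript arrays. Per the labels, bone marrow cells were differentiated for 7 days with L929 cell supernatant as the source of M-CSF, the growth factor that drives macrophage differentiation. The macrophages were replated, cultured for 24 h in medium alone or with IL-4, and sorted for F4/80, a macrophage surface protein, before RNA isolation. The cells came from BALB/c mice or from 4get/Stat6-/- mice, which lack the transcription factor activated by the IL-4 receptor. The IL-4 dose is given as 10 µg/mL in the sample protocols and as 10 mg/mL in the series text. The labels do not settle which unit was meant.

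The authors deposited 1 log2 signal per probeset and array. Per the submitters' processing notes, these values were made with RMA in Affymetrix Expression Console. RMA corrects the background, normalizes the arrays by quantiles and summarises the probes of a probeset on a log2 scale. The versions and settings, and the genome build behind the array design, are not given in the sources used here. The log base was taken from the range of the values. RMA pulls low signals together, so that fold changes of weakly expressed genes are understated.

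The 4 arrays formed 4 groups of 1 array each, by genotype and culture. The table held 35557 probesets. Of these, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12147 were not named in the annotation used here. Genes were named from probesets with 1 symbol, and 21698 of these matched an Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table served for names, gene spans and which genes neighbour each other, and none of its coordinates are given. Each of 19938 genes was represented by 1 probeset, the one with the highest mean signal over the 4 arrays. There were 999 genes with several such probesets. The columns of the table were all mapped to a sample.

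A floor was set at the median of the single-gene probesets over the 4 arrays, 2.52 on the log2 scale, and 10798 genes reached it on at least 1 array. The median log2 signal over all probesets was 2.23 in wild type in medium, 2.23 in wild type with IL-4, 2.29 in Stat6-/- in medium and 2.28 in Stat6-/- with IL-4. Olfactory receptor genes, which macrophages were assumed not to express, gave a gauge of background: the 95th percentile of 1027 such genes lay between 1.91 and 2.07 on the 4 arrays, under the floor.

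With 1 array per group there was no test between groups, and no p-value was computed. A gene was called changed by a fixed rule of size, a log2 difference of at least 1 (2-fold) with the higher of both arrays at or above the floor. The 5 comparisons were: IL-4 against medium in each genotype, Stat6-/- against wild type in each culture, and the difference between the IL-4 effects, wild type minus Stat6-/-, for which the highest of the 4 arrays had to reach the floor. Where the lower array was under the floor, a lower bound of the fold was computed against the floor. Overlaps of called genes are given beside the number that independent lists would share. Correlations are across genes, which are not independent replicates.

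The 13 gene lists were alternative activation genes, the IL-4 receptor and STAT pathway, arginine and polyamine metabolism, inflammatory mediators, interferon-stimulated genes, MHC class II presentation, the cell cycle, cholesterol synthesis, fatty acid uptake and oxidation, glycolysis, the unfolded protein and amino acid stress response, the lysosome, and macrophage fusion. The 12 marker lists covered macrophages, T cells, B cells, neutrophils and their precursors, basophils and mast cells, eosinophils, dendritic cells, NK cells, erythroid cells, fibroblasts, osteoclasts and sex-linked genes. Of 444 list entries, 406 matched a gene on the array, 1 of them by an older symbol. For each list with at least 3 members above the floor, the median log2 difference was set against the medians of 10000 random lists of the same size matched on mean signal in 20 bins. A list is said to lie outside the random lists when its percentile was under 2.5 or over 97.5. These percentiles describe the 4 arrays and are no test of the conditions.

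The design, the lists, the rule of size and the rule for naming genes were fixed before the data were examined. Named were Stat6 and 12 core genes of the IL-4 response in every comparison, the 12 genes with the largest increase and the 12 with the largest decrease past the rule of size in each comparison of a pair of arrays, the 10 largest each way for the difference of IL-4 effects, and up to 4 members with the largest differences past the rule from each list. Any other gene is said to have been chosen after its values were seen.

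Alternatives fixed in advance were quantile normalization applied again, arrays shifted to one median, removal of the intensity trend by lowess (fraction 0.3), no floor, a floor at the 75th percentile (4.65 on the log2 scale), 1.5-fold and 3-fold rules of size, the mean of all probesets of a gene, and 5 bins for the random lists. The alternatives chosen after seeing the data were: raising values below the floor to the floor, and removing the trend on the genomic span of each gene after the intensity trend. The rule of size and the list percentiles were tested on simulated data for IL-4 in wild type over 19938 genes with 1 array per group. The rule recovered 99 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3, and 7 of 200 unchanged lists fell outside the random lists. The changed genes were picked from those with a mean signal at least 1 above the floor. Noise of SD 0.176, estimated from the Stat6-deficient arrays over all genes, was drawn independently for each gene. The recovery thus does not describe genes near the floor or the spread between cultures. In a simulated trend on gene span over 10776 genes, removal took the Spearman correlation with span from -0.558 to -0.00112, and 100 genes shifted by 1.5 kept a median of 1.49.

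The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Probesets with several symbols and those not named here were left out of the comparisons of genes, since no single gene could be assigned to them.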

Results

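Gene expression was measured in mouse bone marrow-derived macrophages of 2 genotypes, each cultured in medium or with the cytokine IL-4, on 4 arrays in all. Wild-type cells came from BALB/c mice. Stat6-deficient cells came from 4get/Stat6-/- mice, which lack the transcription factor that the IL-4 receptor activates and carry a reporter of IL-4 transcription. Each combination of genotype and culture was measured on 1 array, so no difference given here has a replicate check, and the number of arrays limits the precision of every value. Values are RMA signals on the log2 scale and differences are log2 differences. Genes are said to have risen, fallen or changed where they passed the 2-fold rule of size, and to be under the floor where their signal was below 2.52.

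Stat6 itself had a signal of 7.34 in wild type in medium and 6.68 in wild type with IL-4. In Stat6-deficient cells it was 4.54 in medium and 4.25 with IL-4, which was 6.98-fold lower in medium and 5.40-fold lower with IL-4. Both Stat6-deficient arrays thus lay below both wild-type arrays, in the direction of their labels. The remaining signal stayed above the floor, and the probeset can read exons outside the targeted part of the gene. Across the 10798 genes above the floor, the Stat6-deficient arrays in medium and with IL-4 had a Pearson correlation of 0.985. The wild-type arrays in medium and with IL-4 had a correlation of 0.935, while the arrays of both genotypes in medium had one of 0.979.

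The response of wild-type macrophages to IL-4 was compared first, since it sets the genes against which the role of Stat6 was asked. The largest increases were in genes known from alternatively activated macrophages. Retnla, a secreted resistin-like protein, went from 1.20 to 10.33, a rise of at least 223-fold. Arg1, the arginase that breaks down arginine, went from 1.64 to 8.60, a rise of at least 67.4-fold, and Mgl2, a C-type lectin of the macrophage surface, went from 2.26 to 7.63, at least 34.4-fold higher. Cd28 and Ifit3 were among the genes with the largest decreases. Cd28, a costimulatory receptor best known from T cells, went from 6.10 to 1.31, a fall of at least 11.9-fold, and Ifit3, an interferon-induced antiviral gene, fell by 3.84.

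Other genes with large increases started under the floor in medium: the VEGF receptor Flt1 (1.97 and 6.74) rose by at least 18.6-fold, the inhibitory ligand Pdcd1lg2 (1.63 and 6.39) by at least 14.5-fold, the ribonuclease gene Rnase2a (1.23 and 6.21) by at least 12.9-fold and the signalling inhibitor Socs2 (5.94 with IL-4) by at least 10.7-fold. Measured on both arrays were the increases of the gene of coagulation factor X, F10 (4.17), the chemokine Ccl24 (3.88), the cationic amino acid transporter Slc7a2 (3.87), the cell fusion protein Dcstamp (3.80) and the transcription factor Bhlhe40 (3.72). Rnase2a belongs to a family of closely related genes, whose transcripts the array can fail to separate. Of the core genes, Chil3, a chitinase-like lectin, rose by at least 4.57-fold, from 1.09 to 4.71. The transcription factor Irf4 rose by 2.08 and the cytokine signalling inhibitor Socs1 by 1.51. The mannose receptor Mrc1 (8.40 in medium, 9.09 with IL-4) and the nuclear receptor Pparg (5.67 and 6.33) did not pass the rule. The chemokines Ccl17 and Ccl22 and the adhesion protein Cdh1 were under the floor on all 4 arrays, at 2.13 or less.

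**Figure D1:**
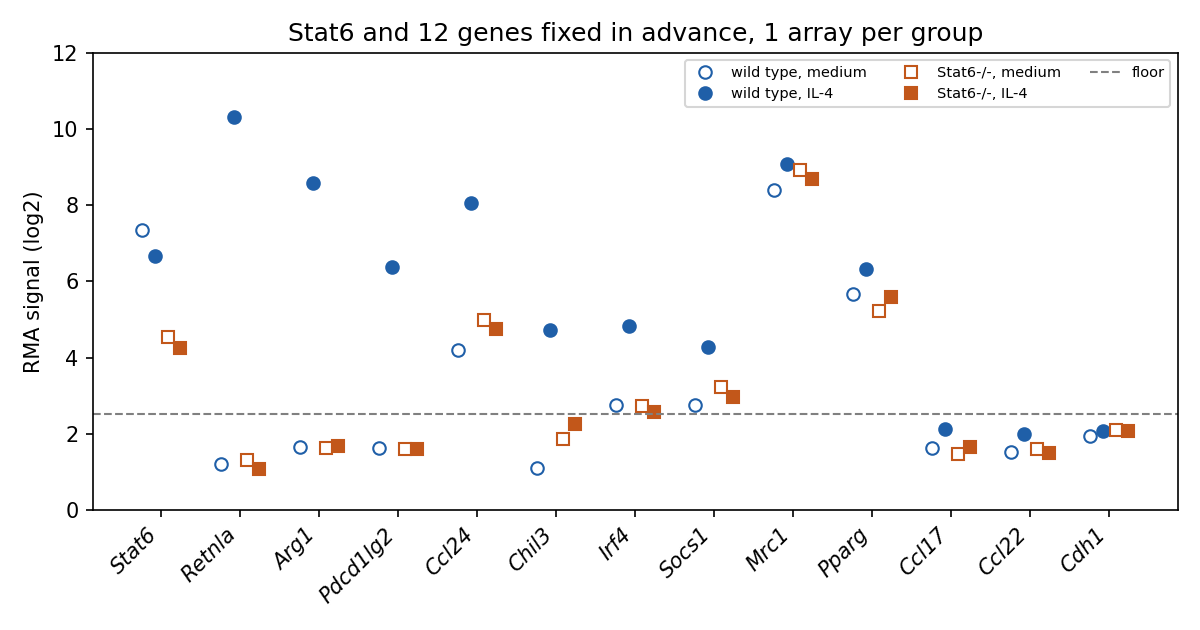
RMA signal (log2, vertical axis) of Stat6 and the 12 core genes on each of the 4 arrays, 1 point per array; open symbols are medium and filled symbols IL-4, circles wild type and squares Stat6-/-, and the dashed line is the floor at 2.52. Retnla reached 10.33 and Arg1 8.60 only on the array of wild-type cells with IL-4.

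The genes with the largest decreases included the adhesion protein Clmp (-4.57), the adhesion GPCR Adgre4 (-4.23), the iron exporter Slc40a1 (-3.88), the matrix glycoprotein Thbs1 (-3.66), the interferon-induced chemokine Cxcl10 (-3.17), the ubiquitin ligase Rnf144b (-3.07), the ectonucleotidase Entpd1 (-3.03) and the phosphodiesterase Pde3b, which went from 6.01 to 3.01. Ifitm6 fell from 5.55 to 1.57, under the floor, a fall of at least 8.15-fold, and the integrin Itga9 from 5.62 to 2.25, a fall of at least 8.53-fold.

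Among the gene lists, 19 of 28 alternative activation genes above the floor rose and 1 fell, with a median difference of 1.88. The gene that fell was Il4ra (-1.57), the IL-4 receptor chain. Of 20 cholesterol synthesis genes 11 rose and 0 fell, with a median of 1.06, led by Sqle (2.61), Fdps (1.94), Cyp51 (1.73) and Idi1 (1.71), which are enzymes of the sterol and isoprenoid steps. Interferon-stimulated genes moved the other way, with 18 of 29 lower and 0 higher and a median of -1.26; after Ifit3 and Cxcl10, Ifit2 (-2.49) and Rsad2 (-2.46) led. MHC class II presentation genes had a median of 0.60, and 2 of 7 rose, Cd74 (1.38), the invariant chain, and H2-DMa (1.11), which helps load peptides. Of 20 genes of the unfolded protein and amino acid stress response, 3 rose, Sdf2l1 (1.78), Psat1 (1.10) and Creld2 (1.02), with a list median of 0.35, which became 0.22 with values raised to the floor. These 5 lists lay outside the middle 95% of matched random lists, against 0.65 of 13 for lists of unrelated genes.

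The other 8 lists had medians inside that range. Of 26 inflammatory mediators, 8 fell and 3 rose, with a median of -0.28 (percentile 11.5). Tlr2 (-2.89) and Cd14 (-2.74), both receptors for bacterial products, Nfkbiz (-2.77), an NF-kappaB cofactor, and the cytokine Il1b (-2.60) fell the most, while Ptgs2 (from 2.51, just under the floor, to 4.13), Cxcl3 (1.17) and Ccl7 (1.01), chosen after their values were seen, rose. This list lay at percentile 0.04 with a floor at the 75th percentile and at 0.07 with the intensity and gene length trends removed. The other way, its median was -0.14 with values raised to the floor. Over the 8 alternatives the median ran from -0.80 to -0.03 and the percentile up to 60.5. In the IL-4 receptor and STAT pathway, 3 of 16 genes rose, the inhibitors Socs2, Cish (from 2.19 to 3.97, at least 2.73-fold) and Socs1 (1.51), and 3 fell, Il4ra together with Il13ra1 (-1.36) and Pias1 (-1.06), the last pair chosen after their values were seen; the median was -0.20 and the mean 0.08. In arginine and polyamine metabolism, Arg1, Slc7a2, Srm (1.22), which makes spermidine, and Slc7a1 (1.15) were the 4 of 11 that rose, Smox (-1.38), which oxidises spermine, fell, and the median was 0.09.

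Macrophage fusion genes had a median of 0.03, but 3 of 14 rose strongly: Dcstamp, Ocstamp (from 2.43 to 5.66, at least 8.81-fold), both required for multinucleated cells, and the matrix metalloproteinase Mmp9 (2.73). Of 15 glycolysis genes, Pfkp rose from 5.75 to 7.33, Pfkfb3 (-1.71) and the lactate transporter Slc16a3 (-1.04) fell, and the median was 0.07 with a mean of -0.00253; with the mean of all probesets per gene this list lay at percentile 98.0. Of 21 genes of fatty acid uptake and oxidation, Ppargc1b (1.03) rose and Cpt1a (-1.28), which carries fatty acids into mitochondria, fell, with a median of 0.02 and a mean of -0.01. Of 26 lysosome genes, the cathepsins Ctsh (-1.78) and Ctsc (-1.46) fell, with a median of -0.32. Of 30 cell cycle genes, Cenpa (-1.19), a centromere histone, fell, with a median of -0.06.

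Among the marker lists, 4 of 7 osteoclast markers above the floor rose, Dcstamp, Ocstamp, Mmp9 and Itgb3 (from 2.14 to 4.11, at least 3.01-fold). The list median of 1.98 is the value of Itgb3, which was under the floor in medium. These markers are also expressed by macrophages, and Dcstamp, Ocstamp and Mmp9 stand in the fusion list too. Of 17 macrophage markers, 3 fell: Fcgr1 (-1.76), a high-affinity IgG receptor, Mertk (-1.36), a receptor for dying cells, and Adgre1 (-1.21), which encodes F4/80; the median was -0.44. Of 6 T cell markers above the floor, Cd28 and Cd4 (-2.42) fell and the median was -0.52, which became 0.05 with no floor. The medians were -0.09 over 4 B cell markers, 0.06 over 4 neutrophil markers, of which Mmp8 (1.38) rose and Ngp fell from 2.79 to 1.76 (at least 1.21-fold), and 0.17 over 4 fibroblast markers, of which Postn rose from 1.72 to 3.55 (at least 2.04-fold). The basophil and mast cell, eosinophil, dendritic cell and NK cell lists had 2 members each above the floor, the erythroid list 0 and the sex-linked list 1, and none of these had a median.

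In total, 1001 of 10282 genes that could have passed the rule changed in wild type, 304 higher and 697 lower. Quantile normalization applied again gave 403 higher and 488 lower, removal of the intensity trend 408 and 501, and removal of the intensity and gene length trends 402 and 438, so that the share of increases went from 30.4% to between 44.9% and 47.9%. Arrays shifted to one median gave 278 and 783, a share of 26.2%.

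The same treatment was then compared in Stat6-deficient cells, to see what response remained without this factor. The core genes did not pass the rule there. Arg1 was at 1.63 in medium and 1.69 with IL-4, Retnla at 1.32 and 1.08, and Pdcd1lg2 at 1.60 and 1.61, all under the floor, and Chil3 was under it at 1.86 and 2.26. Above the floor, Ccl24 was at 5.00 and 4.75, Irf4 at 2.73 and 2.57, Mrc1 at 8.93 and 8.70, and Pparg at 5.22 and 5.58. The genes that did rise included Mmp12 (1.44), the macrophage elastase, Atp6v0d2 (1.18), a proton pump subunit, the chemokine Ccl8 (1.16), the opioid precursor Penk (from 2.49 to 3.59, at least 2.09-fold) and the fatty acid binding protein Fabp5 (1.03).

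The other largest increases in Stat6-deficient cells were Glrx3 (1.79), a glutaredoxin, the small non-coding RNA genes Rny1 (1.77), Snord16a (1.43) and Vaultrc5 (1.18), the stress-induced transcription factor Ddit3 (1.24), the histone gene H2bc14 (1.19) and Prp2 (1.17). The chaperone Dnajb6 (3.52 with IL-4) and the Mediator subunit Med29 (2.01 in medium and 3.15 with IL-4) started under the floor, and their bounds of at least 1.99-fold and 1.55-fold lie below the rule. The genes that fell were Usp17ld (-1.96), the focal adhesion protein Tns1 (-1.64), Itga9 (-1.26), Gm10602 (-1.18), Gm15455 (-1.18), Lyrm9 (2.72 in medium and under the floor with IL-4, at least 1.14-fold), Ppp2r3c (-1.12), Enpp4 (-1.05), the opsin Opn3 (-1.03), Pilrb1 (-1.02), Tgfbrap1 (-1.01) and Gxylt1, which went from 4.38 to 3.38. Usp17ld belongs to a family of near-identical copies, whose transcripts the array can fail to separate. In total 37 of 10410 genes changed, 25 higher and 12 lower.

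Of 28 alternative activation genes, Mmp12 and Atp6v0d2 rose in Stat6-deficient cells and 0 fell, with a median of 0.21 (percentile 100), which became 0.04 with no floor and 0 with values raised to the floor, both inside the random lists. The inflammatory mediators had a median of 0.25 (percentile 100) with 0 of 26 past the rule. These were the 2 of 13 lists outside the random lists. The Stat6-deficient array in medium also enters the genotype difference in medium. There the inflammatory mediators had a median of -0.38, and Mmp12 and Atp6v0d2 were lower in Stat6-deficient cells. For the inflammatory mediators, low values on that array alone would give both results. Mmp12 (-2.88) and Atp6v0d2 (-1.56) were also lower in Stat6-deficient cells with IL-4, a comparison without that array. Low values on it therefore cannot be the whole source of their genotype difference. The medians of interferon-stimulated genes and of cholesterol synthesis genes were both -0.06, with 0 genes past the rule in either list and a mean of 0.05 for cholesterol synthesis. The median of MHC class II genes was 0.08. Ddit3 was the 1 of 20 genes of the unfolded protein and amino acid stress response that rose, and Fabp5 the 1 of 21 genes of fatty acid uptake and oxidation.

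**Figure D2:**
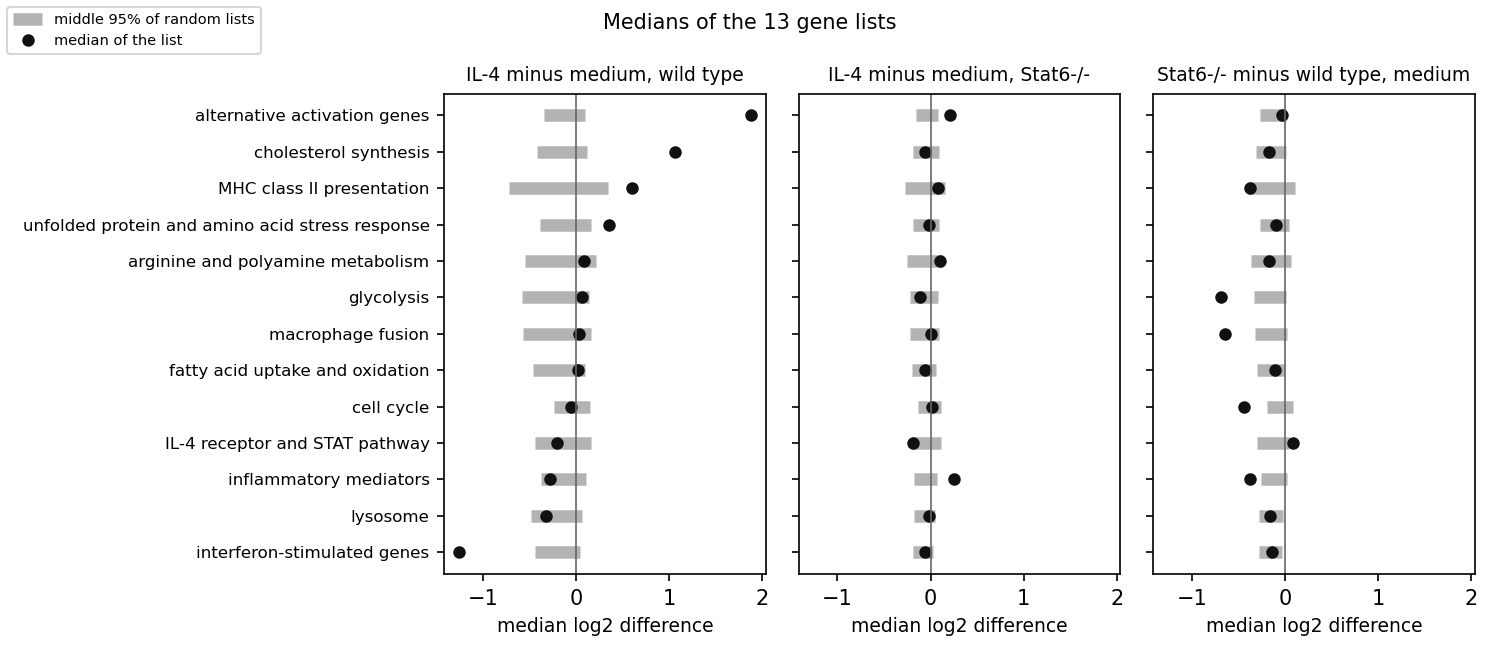
Median log2 difference (horizontal axis) of each of the 13 gene lists in 3 comparisons, with the middle 95% of 10000 matched random lists as grey bars. In wild type with IL-4 the alternative activation genes lay at 1.88 and the interferon-stimulated genes at -1.26, and in Stat6-/- these lists lay at 0.21 and -0.06.

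The difference between both IL-4 effects, wild type minus Stat6-deficient, gives the part of the response that went with the genotype. Many of these genes were under the floor on at least 1 array, and their values are given with such signals raised to the floor, an alternative chosen after seeing the data. So computed, the difference was 7.80 for Retnla, 6.07 for Arg1, 4.95 for Mgl2, 4.22 for Flt1, 3.86 for Pdcd1lg2, 3.80 for Dcstamp, 3.72 for the cystine transporter Slc7a11, 3.69 for Rnase2a and 3.33 for the cystatin Cst7, and it was 4.13 for Ccl24, which was above the floor on all arrays. In the other direction, among genes above the floor on all arrays, were Ifit3 (-3.79), Clmp (-3.79), the histidine-degrading enzyme Hal (-3.55), Adgre4 (-3.54), Slc40a1 (-3.52), Thbs1 (-3.33), the prostaglandin D synthase Hpgds (-3.27) and the acute phase protein Saa3 (-3.02), while Ifitm6 and Cd28 were at -3.16 and -3.14 with signals raised to the floor. Irf4 (2.25), Chil3 (2.19 with signals raised to the floor) and Socs1 (1.75) also passed the rule, and Mrc1 (0.93), Pparg (0.30) and Stat6 (-0.37) did not.

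Of the 13 gene lists, those with the largest medians of this difference in size were alternative activation genes (1.64, with 19 higher and 1 lower of 28), cholesterol synthesis (1.19, with 13 of 20 higher, among them Sqle at 2.32, Fdps at 2.05, Cyp51 at 1.89 and Mvd at 1.74) and interferon-stimulated genes (-1.20, with 19 of 29 lower, among them Mx2 at -2.44). MHC class II genes had a median of 0.68 with 0 of 7 past the rule, and inflammatory mediators one of -0.50, with 11 lower and 2 higher of 26. The inflammatory median ran from -1.10 to -0.28 over the 8 alternatives, outside the random lists in each. Glycolysis (0.18) and the unfolded protein and amino acid stress response (0.17) made 7 lists outside the random lists, of which the last was inside under 3 of 8 alternatives. Of the marker lists, the osteoclast markers had a median of 1.84 with 4 of 7 higher, which became 0.34 with no floor, still outside the random lists, and the macrophage markers one of -0.48 at percentile 1.54, with 2 of 17 lower, Fcgr1 (-1.85) and Mertk (-1.10). The rule was passed by 969 of 10798 genes, 346 higher and 623 lower. Quantile normalization applied again gave 420 and 461, and removal of the intensity and gene length trends 401 and 458, so that the higher share went from 35.7% to 47.7% and 46.7%, while arrays shifted to one median gave 308 and 704, a share of 30.4%.

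Across the 10798 genes the IL-4 effects of both genotypes had a Pearson correlation of 0.272 and a Spearman correlation of 0.292. The lists of changed genes shared 6 that rose in both genotypes, against 0.704 for independent lists, and 4 that fell in both, against 0.775. Those that fell were Itga9, Enpp4, Tns1 and Pilrb1, and those that rose included Mmp12, Penk and Ccl8, the last from 1.67 in wild type, under the floor, by at least 1.40-fold. In 1 case the direction was opposite, Gm10602, which went from 2.34 to 3.53 in wild type and from 3.71 to 2.52 in Stat6-deficient cells. The 304 genes that rose in wild type had a median of 0.14 in Stat6-deficient cells and 190 of them were above 0 there, while the 697 that fell had a median of -0.20 and 550 were below 0.

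**Figure D3:**
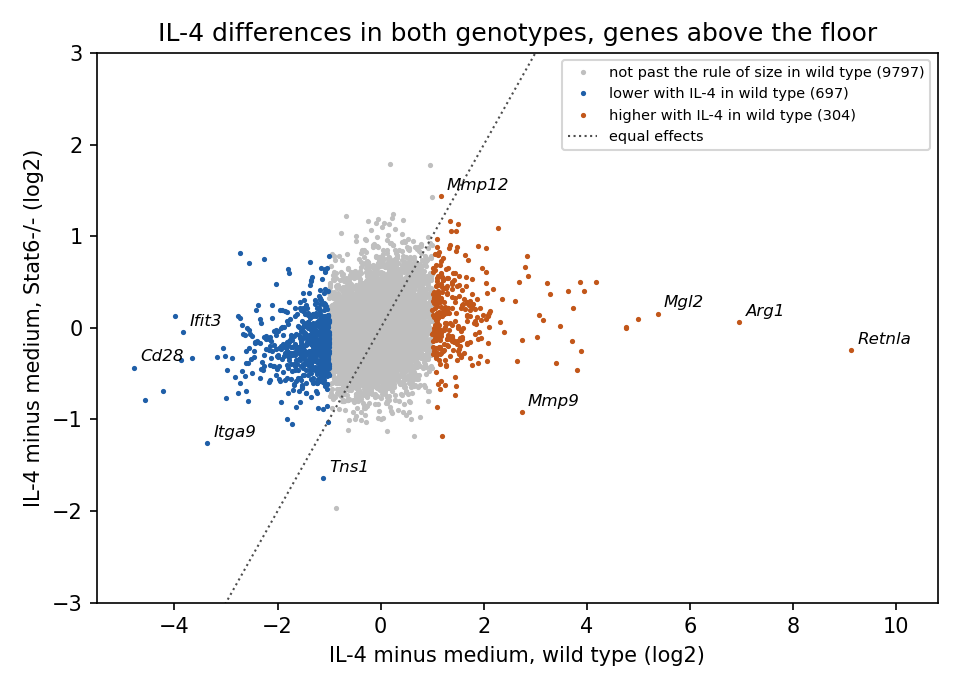
IL-4 minus medium in wild type (horizontal axis, log2) against the same in Stat6-/- (vertical axis, log2) for the 10798 genes above the floor, 1 point per gene, with genes changed in wild type coloured and the dotted line at equal effects. The 304 genes higher and 697 lower in wild type lie close to 0 in Stat6-/-, with medians of 0.14 and -0.20.

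The genotypes were also compared in medium, which gives the difference without added IL-4 after the same time in culture. The largest differences were toward lower signals in Stat6-deficient cells. Cxcl13, a B cell chemoattractant, was at 5.87 in wild type and 1.91 in Stat6-deficient cells, at least 10.2-fold lower. The matrix glycoprotein Fn1 (-3.68), the integrin Itgax (-3.50), which encodes CD11c, and Mmp12 (-3.15) were also lower, as was Penk, at 5.96 and 2.49, by at least 10.9-fold. The largest increases were smaller and included Lsp1 (1.92), a leukocyte actin-binding protein, and the C-type lectins Clec10a (1.67) and Mgl2, the last at 2.26 and 3.69, at least 2.25-fold higher.

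Further genes lower in Stat6-deficient cells in medium were Atp6v0d2 (-2.31), the inhibitory receptor Siglece (-2.04), the membrane metalloproteinase Mmp14 (-1.79), the ubiquitin ligase Rnf128 (-1.72), the PCNA-associated factor Pclaf (-1.69) and the transcription factor Egr2 (-1.63). Further higher genes were the protease Ctse (1.68), Ifitm6 (1.65), the LIF receptor Lifr (1.53), the kynurenine enzyme Kmo (1.38), the matrix protein Tgfbi (1.37), Gm10602 (2.34 and 3.71, at least 2.27-fold), Treml2 (1.32) and the endothelin receptor Ednrb (1.22), and Usp17ld was at 3.15 in wild type and 4.63 in Stat6-deficient cells. Of the core genes besides Stat6, none passed the rule; Ccl24 differed by 0.80 and Mrc1 by 0.54, and Chil3, at 1.09 and 1.86, was under the floor on both arrays.

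The glycolysis list had a median of -0.69 in this comparison, with Slc2a1 (-1.11), the glucose transporter, as the 1 of 15 genes past the rule. Macrophage fusion genes had a median of -0.64, and 3 of 14 were lower, Atp6v0d2, Mmp9 (-1.31) and the tetraspanin Cd9 (-1.25). Cell cycle genes had a median of -0.44, with Pcna (-1.02), the replication clamp, lower, and this list lay at percentile 2.65 with a floor at the 75th percentile. Of 26 inflammatory mediators 4 were lower, Marco (3.95 and 2.34, at least 2.69-fold), Il1rn (-1.55), Ccl5 (-1.26) and Acod1 (-1.02), with a median of -0.38, which lay at percentile 3.27 with no floor. The IL-4 receptor and STAT pathway had a median of 0.08, at percentile 99.1, and a mean of -0.17 that holds Stat6 itself. The alternative activation genes had a median of -0.04, with 6 lower and 2 higher of 28. MHC class II genes had a median of -0.38 at percentile 3.33, and 1 of 7 was lower, H2-Aa, at 7.83 in wild type and 6.83 in Stat6-deficient cells. With a floor at the 75th percentile the median of this list was -0.56 at percentile 0.25, outside the random lists. Interferon-stimulated genes (-0.13) and cholesterol synthesis genes (-0.17) had 0 members past the rule. The lists of fatty acid uptake and oxidation, with Lpl (-1.03) and Cd36 lower, of arginine and polyamine metabolism, with Azin1 (-1.23) and Slc7a2 (3.67 and 2.51, at least 2.21-fold) lower, and of the lysosome and the stress response also lay inside the random lists.

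Of 7 osteoclast markers above the floor, 3 were lower in Stat6-deficient cells in medium, Ctsk, Mmp9 and Acp5 (-1.13), with a median of -0.91. Ctsk was at 3.52 in wild type and 2.01 in Stat6-deficient cells, at least 1.99-fold lower, a bound just below the rule, and the median is the value of Dcstamp, at 2.19 in Stat6-deficient cells. The median became -0.57 with values raised to the floor, still outside the random lists, and 0.00432 with no floor, inside them. Macrophage markers had a median of -0.11 with 0 of 17 past the rule. The medians of the T cell (0.21), B cell (-0.03), neutrophil (0.18) and fibroblast (0.09) markers lay inside the random lists, with means of the other sign for T cells (-0.10), B cells (0.13) and neutrophils (-0.000345). The T cell median went to 0.24 with no floor and to -0.66 with a floor at the 75th percentile, both outside, at percentiles 98.5 and 0.765. The T cell marker Il7r (-1.13) and the eosinophil marker Ccr3 (-1.02) were the single members past the rule in their lists. In total 149 of 10299 genes differed, 31 higher and 118 lower. Quantile normalization applied again gave 42 and 71, removal of the intensity trend 38 and 78, and removal of the intensity and gene length trends 37 and 79, which moved the higher share from 20.8% to between 31.9% and 37.2%. Arrays shifted to one median gave 24 and 171, a share of 12.3%. Genotype went with mouse line in these samples, so a difference of Stat6 and one of the rest of the line cannot be told apart. The Stat6-deficient array in medium also enters the IL-4 effect in Stat6-deficient cells, so both results are not independent.

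The genotypes were compared with IL-4 present as well, and the largest differences included genes of the wild-type response. Retnla was at 10.33 in wild type and 1.08 in Stat6-deficient cells, at least 223-fold lower, and Arg1 was at least 67.4-fold lower. Fn1 (-5.82), Itgax (-5.56), Mmp9 (-4.97), F10 (-4.84), Penk (-4.64) and Slc7a2 (-4.54) were also lower. Genes under the floor in Stat6-deficient cells were lower by at least 20.8-fold for Dcstamp (6.90 and 1.73), 14.5-fold for Pdcd1lg2 (6.39 and 1.61), 13.8-fold for Slc7a11 (6.31 and 1.47) and 12.9-fold for Rnase2a (6.21 and 1.37). Genes under the floor in wild type were higher in Stat6-deficient cells by at least 28.1-fold for Ifitm6 (1.57 and 7.33), 11.1-fold for Cd28 (1.31 in wild type) and 4.66-fold for Kmo (4.74 in Stat6-deficient cells). Measured on both arrays were the higher values of Slc40a1 (4.08), Ctse (3.81), Clmp (3.52), Ifit3 (3.49), the IgG receptor Fcgr4 (3.25), Adgre4 (3.24), Thbs1 (3.21), Entpd1 (3.04) and Hal (2.99).

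Among the lists, 20 of 28 alternative activation genes were lower and 1 higher, Il4ra (1.49), with a median of -1.98. Cholesterol synthesis genes had a median of -1.38 with 14 of 20 lower, Sqle (-2.86) and Hmgcs1 (-2.03) the most, and 17 of 29 interferon-stimulated genes were higher with a median of 1.10. Of 7 MHC class II genes 4 were lower, Cd74 (-1.75), H2-Aa (-1.19), H2-Ab1 (-1.06) and H2-Eb1 (-1.02), with a median of -1.02. Glycolysis (-0.66), macrophage fusion (-0.59), arginine and polyamine metabolism (-0.68), the unfolded protein and amino acid stress response (-0.34) and the cell cycle (-0.24) brought the lists outside the random lists to 9; the last 3 of these were inside under 1 alternative each. Of 26 inflammatory mediators 8 were higher and 3 lower, Cd14 (2.62) and Tlr2 (2.35) the most, with a median of 0.17 at percentile 95.6, inside the random lists. It was 0.67 at percentile 100 with a floor at the 75th percentile and 0.23 at percentile 98.2 with the intensity and gene length trends removed, both outside. Of 7 osteoclast markers 6 were lower, with a median of -1.66, and the macrophage markers had a median of 0.35 at percentile 98.0, which was inside under 4 of 8 alternatives. In all 922 of 10433 genes differed, 418 higher and 504 lower.

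The genotype differences in medium and with IL-4 rest on separate arrays. Whether both cultures of a genotype came from 1 cell preparation is not known here, and a difference between preparations could then enter both comparisons. The genotype differences shared 49 genes lower in Stat6-deficient cells in both cultures, against 5.51 for independent lists, and 11 higher in both, against 1.20. Fn1, Itgax, Penk, Mmp12 and Stat6 were lower in both, and Lsp1 was higher in both by the same 1.92. Mgl2 and Gm10602 were higher in medium, from signals under the floor in wild type, and lower with IL-4 (-3.78 and -1.01), and 6330407A03Rik, chosen after its values were seen, was lower in medium (-1.01) and higher with IL-4 (2.38 in wild type, under the floor, and 3.99). The Pearson correlation of both genotype differences across genes was 0.301 and the Spearman correlation 0.263.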

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

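The tests chosen only after the result was seen were the removal of the intensity and gene length trends and the comparison of the genes changed in wild type with random lists, both for the residual response of Stat6-deficient cells. A set of 250 genes held the named genes and every measured member of the marker lists, whatever its value. Of these, 14 had IL-4 effects of at least 0.5 in opposite directions in the genotypes, as did 100 of all 10798 genes above the floor. With 1 array per group these differences were not tested. A low signal on the Stat6-deficient array in medium alone would raise the Stat6-deficient effect. Hal, which degrades histidine, went by -2.74 in wild type and 0.81 in Stat6-deficient cells, a difference of -3.55. The prostaglandin D synthase Hpgds (-2.56 and 0.71) differed by -3.27, the acute phase protein Saa3 (-2.26 and 0.75) by -3.02, and Mmp9 (2.73 and -0.92) by 3.65. Signals under the floor enter some of the others. The fatty acid binding proteins Fabp5 and Fabp4 differed by -1.80 and -1.33, the scavenger receptor Marco by -1.46, Cxcl13 by -1.88, Dnajb6 by -1.89, Pclaf by -1.28, the serine synthesis enzyme Phgdh by -1.15, the stress-induced Sesn2 by -1.31, Gm10602 by 2.37 and Gm15455 by 1.82. With signals under the floor raised to it, Cxcl13 and Phgdh had effects of 0 in Stat6-deficient cells and Dnajb6 one of -0.07 in wild type, so no opposite effect was measured for these 3 genes, and the differences became -1.36, -0.43 and -1.06.

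Probesets outside the comparisons of genes also differed past the rule of size between IL-4 and medium. Of 12147 probesets not named here, 1021 passed in wild type, 267 higher and 754 lower, and 783 passed in Stat6-deficient cells, against 37 of 10410 genes there. What these probesets measure is not known here, and whether they vary more between arrays than gene probesets do was not tested, so these counts do not show a response to IL-4. Of 1621 probesets with several gene symbols, 48 passed in wild type, 12 higher and 36 lower, and 9 passed in Stat6-deficient cells.

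The first pattern is the genotype difference in medium, 149 genes. A difference in sex between the animals is argued against, since Xist (7.89 in wild type and 7.71 in Stat6-deficient cells) and 3 Y-linked genes, all under the floor, differed by at most 0.19 (0.1861) in size. For DNA around Stat6 carried over from the embryonic stem cell strain, the genes within 20 Mb of Stat6 were counted. Of these, 1 of 104 passed, Olfr767 (chosen after its values were seen), against 147 of 10194 elsewhere, a ratio of 0.667. The exact 95% interval of the local share, 0.0243% to 5.24%, counts genes as independent and does not exclude a local excess. Changes of these neighbours themselves do not make up the difference, since most genes past the rule lie elsewhere. The count cannot exclude carried-over DNA as a cause, since a variant there could act on genes elsewhere. Cells of another type stay open, as a hypothesis: of 5 marker lists measured, the osteoclast list had the largest median in size, -0.91 (-0.9055), the bound set in advance was met, and the cells were sorted for F4/80, but macrophages express Ctsk, Mmp9 and Acp5 as well, the median was -0.57 with values raised to the floor and 0.00432 with no floor, and the T cell median turned from 0.21 to -0.66 with a floor at the 75th percentile. Stat6 itself, the rest of the mouse line, the reporter and the cell preparation cannot be told apart here, since each genotype came from 1 line and each group held 1 array.

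The second pattern is the smaller IL-4 response of Stat6-deficient cells, 37 genes against 1001. With a 1.5-fold rule it was 595 against 2907, and 306 of the Stat6-deficient genes were higher and 289 lower. Compressed fold changes on the Stat6-deficient arrays are not settled by the slope that was set as their test. Across the 1001 genes changed in wild type, the slope of the Stat6-deficient on the wild-type effect was 0.0953. Of 1000 resamplings of genes, 95% gave 0.0791 to 0.113, and genes are not independent replicates. The slope lies under the bound of 0.2 set in advance against compression. A low slope restates the smaller response, however, and strong compression would give it too, so the slope cannot separate them. The deposited signals ran from 0.30 to 12.93 in Stat6-deficient cells in medium and from 0.20 to 13.08 with IL-4. In wild type they ran from 0.25 to 13.04 and from 0.16 to 13.12. These ranges argue against a compressed scale in the signals that gave the effects. RMA makes the arrays alike in range, so the arrays before normalization are not covered. That the loss of Stat6 reduced the response stays open as the biological hypothesis, beside an unequal exposure to IL-4, which was not tested, and the rest of the mouse line.

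The third pattern is the residual IL-4 response of Stat6-deficient cells. Over the 37 genes past the rule, 27 had the same sign in wild type, a share of 0.730 (exact 95% interval 55.9% to 86.2%), which lies between the bounds of 0.6 and 0.75 set in advance, so that noise between single arrays cannot be excluded for these genes. The interval counts genes as independent, which they are not, so it gives no spread between cultures. Noise that strikes each gene independently is argued against for the wider set of genes changed in wild type. Both IL-4 effects share no array. With both trends removed, the 303 raised genes with a known span had a median of 0.15 (0.1461) in Stat6-deficient cells. The random lists gave -0.04 to 0.04. These lists draw genes independently, so variation that moves many genes together between the IL-4 and medium arrays is not excluded. Shared intensity and gene length trends are argued against as the whole cause, since the 697 lowered genes kept a median of -0.11 (-0.1062) with both removed against -0.02 to 0.03, although it was -0.20 before removal, and genomic span only stands in for transcript length. A response to IL-4 without Stat6 may remain as an explanation and was not tested.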

How the results depend on the processing

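The alternatives chosen after seeing the data were values raised to the floor and removal of the intensity and gene length trends; the others were fixed in advance. No paired analysis within a genotype was possible because each group held 1 array, so that the groups share 1 replicate number at most. The difference of the Stat6 signal in medium stayed below 0 but moved to -2.68 with quantile normalization applied again, -2.64 with the intensity trend removed and -2.62 with both trends removed; the cause was not tested. The gene lists outside the random lists under IL-4 in Stat6-deficient cells went from 2 to 1 with no floor and to 1 with values raised to the floor, as members under the floor then enter or are set to a difference of 0. The other way, cell cycle genes (percentile up to 98.2) and arginine and polyamine metabolism (up to 97.53) came outside under 1 of 8 alternatives each. A 1.5-fold rule, which is looser by construction, gave 2907 genes for IL-4 in wild type, 595 for IL-4 in Stat6-deficient cells, 1114 for the genotypes in medium, 2398 with IL-4 and 2830 for the difference of IL-4 effects, and the stricter 3-fold rule gave 271, 4, 17, 283 and 257. A floor at the 75th percentile, which tests fewer genes, gave 20 genes for IL-4 in Stat6-deficient cells and 93 for the genotypes in medium. Other total counts stayed within 1.5 times, but some counts by direction did not: genes lowered by IL-4 in wild type went from 697 to 438 with both trends removed, genes lower in Stat6-deficient cells in medium from 118 to 71 with quantile normalization and 78 with the intensity trend removed, and genes with a higher difference of IL-4 effects from 346 to 199 with the higher floor; the cause was not tested for the scalings. Under each setting, 0 genes passed in the direction opposite to the main one. Of the genes counted for IL-4 in wild type, 790 of 1001 were shared with quantile normalization applied again and 709 with both trends removed; for the genotypes in medium 100 and 93 of 149 were. With no floor the T cell median for IL-4 in wild type became 0.0495 and the osteoclast median for the genotypes in medium 0.00432, as markers under the floor enter. Of lists inside the random lists, several medians near 0 and some larger ones also changed sign, among them the T cell median of the difference of IL-4 effects, from -0.41 to 0.23 with no floor, and that for the genotypes in medium, from 0.21 to -0.66 with the higher floor. Besides the reversals of the lists outside, and with such sign changes counted by their size, 23 list medians moved by over 0.1 with no floor and 70 did not, 23 and 72 with quantile normalization, 26 and 69 with the intensity trend removed, 33 and 62 with both trends removed, 25 and 55 with the higher floor, 11 and 84 with values raised to the floor, 2 and 93 with the mean of probesets, and 0 and 95 with 5 bins. Of the values of the named genes and all marker list members, 272 moved by over 0.1 and 978 did not with quantile normalization, and 428 and 822 with both trends removed. Signals under the floor of 2.52 limit what can be said of weakly expressed genes.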

Other observations

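The groups of genes by shared symbol and the test of Stat6-dependent expression without IL-4 were chosen after the data were seen. Genes were grouped by the start of their symbol, which gave 130 groups of at least 10 genes above the floor. For IL-4 in wild type, 37 of them had a median outside the middle 95% of matched random lists, against 6.5 for groups of unrelated genes. The random lists draw genes independently, so variation that moves related genes together between the arrays is not excluded. Of the 37 groups, 11 lay in a range that about 1 in 1000 random lists reaches. All 11 kept their direction under each scaling alternative and stayed outside the middle 95% with the intensity and gene length trends removed. That check used the same arrays, and genomic span only stands in for transcript length. In most of these groups the median was shifted while few single genes passed the rule. Medians above 0 were found for Ndufa genes, subunits of respiratory complex I (0.74, with 0 of 13 past the rule), Cox genes, mostly of cytochrome c oxidase (0.43, with 4 of 20 higher), Atp genes, which hold ATP synthase and other ATPases (0.29, with 6 higher and 3 lower of 54), and the proteasome core genes Psmb (0.81, with 2 of 10 higher). The same held for the mitochondrial ribosome genes Mrpl (0.38, with 0 of 48 past the rule) and Mrps (0.41, with 1 of 29 higher) and the cytosolic ribosome genes Rpl (0.20, with 0 higher and 1 lower of 33) and Rps (0.33, with 2 higher and 1 lower of 30). Medians below 0 were found for the interferon-inducible Ifi genes (-1.26, with 7 lower and 1 higher of 12), for Parp genes, of which several are interferon-induced (-0.81, with 4 of 11 lower), and for zinc finger Zfp genes (-0.33, with 13 of 204 lower). In Stat6-deficient cells the medians were 0.41 for Psmb, 0.32 for Rps, 0.24 for Ndufa, 0.23 for Cox, 0.20 for Mrps, 0.19 for Rpl, 0.08 for Mrpl, -0.03 for Atp, -0.00579 for Ifi, -0.02 for Parp and -0.05 for Zfp, and the difference between the genotypes was not tested. Outside the 11 groups, the small RNA groups Snord (20 genes) and Snora (13 genes) were chosen after their values were seen. Their medians were 0.41 and 0.35 in Stat6-deficient cells and 0.11 and 0.25 in wild type.

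Short genes had higher differences than long ones under IL-4. Across 10776 genes the Spearman correlation of the IL-4 effect with genomic span was -0.268 in wild type and -0.195 in Stat6-deficient cells, and the median effect in wild type was 0.15 in the shortest 10% of genes and -0.29 in the longest 10%. The correlation was -0.155 for the genotypes in medium and 0.0613 with IL-4.

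A hypothesis was that Stat6 keeps some genes expressed without added IL-4, in which case genes lower in Stat6-deficient cells in medium should mostly be genes that IL-4 raises in wild type. Of 117 such genes, Stat6 left out, 16 rose under IL-4 in wild type against 3.29 for independent lists, among them Fn1, Itgax, Mmp12, Penk, Egr2 and F10, and 17 fell against 7.55, among them Cxcl13, Siglece and Mmp14. The predicted majority of raised genes was not found: the count fell on the other side by 1 gene, and the exact 95% interval of the raised share, 30.8% to 66.5%, spans an even split. That interval counts genes as independent, which they are not. The wild-type array in medium enters both comparisons and pushes such genes toward the lowered side. In 100 simulations of unchanged genes with noise of SD 0.176, 0 raised and 0.01 lowered genes passed on average, but this leaves out noise on genes that truly differ and the spread between cultures, so that part of the lowered count may come from the shared array, beside the 16 raised genes. That counting error was allowed for only once these counts had been seen, and without it they go against the hypothesis, which stays undecided at best.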
